A study of Rattus norvegicus with 9 samples.

How the data were processed

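The series holds 9 total RNA libraries from the ileum of Otsuka Long-Evans Tokushima fatty rats, a strain that becomes obese and diabetic and lacks a working receptor for cholecystokinin. Tissue was taken 1 month after the operation. Roux-en-Y gastric bypass (RYGB) joins a small stomach pouch to a limb of the jejunum, so that food bypasses most of the stomach and the duodenum. The labels give 3 groups of 3: RYGB ileum with FDG decreased, RYGB ileum with FDG increased, and ileum after a sham operation. FDG is taken here as fluorodeoxyglucose, the glucose analogue used in positron emission tomography; the labels do not spell it out. Samples were grouped by their titles and treatment labels. Per the labels' protocols, tissue was flash frozen on dry ice, RNA was extracted with a Qiagen kit, and libraries were made with a stranded total RNA kit that depletes ribosomal RNA.

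Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, STAR 2.6.0a, Cufflinks 2.2.1, Cuffdiff (version not given in the sources used here) and DESeq2 1.24.0, with their settings and order not given in the sources used here. The same notes list hg19, a human build, although the gene symbols in the tables are those of rat; no coordinates are therefore printed. The 2 deposited tables hold FPKM per gene and library, that is, fragments per length of transcript scaled to the mapped fragments of the library, and the authors gave each table its own scaling. Each table has 6 library columns and 17145 genes, of which 2125 were listed at 0 throughout. The RYGB table sets FDG-decreased against FDG-increased ileum; the sham table sets FDG-increased ileum against sham. The number of columns of samples left unused was 0. Symbols were looked up in a RefSeq gene table of the rat, where 14497 were current; 25 symbols that a spreadsheet had turned into dates were left out.

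The columns were compared before any test. A pair of FDG-increased libraries occurs in both tables. Columns 2 and 3 of that group in the sham table equal columns 1 and 2 in the RYGB table times 1.023 and 1.0204. Of the genes above 0, 99.985% and 99.941% lay within 1% of that factor. The remaining FDG-increased column differs between the tables. The 12 columns thus hold 10 distinct libraries, 4 of them FDG-increased, against 3 such samples in the labels. The FDG-increased columns of the sham table were used as members of their group and their numbers were used to pair samples in the replicate-block alternative alone. No test was run across the tables. For FDG-decreased against sham ileum, the RYGB table was put on the scale of the sham table with the factor 1.0217 from the shared libraries. Values were given without a test.

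FPKM has no counts behind it here, so read depth is unknown and no counting interval can be given; the ratios of low values between libraries gathered at no common step from which whole reads could be recovered. The sum of FPKM per library ranged from 465697 to 864511, and 10332 to 10892 genes reached 1 FPKM.

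The design allowed for several units, and its branch for normalized values was used. Values were analysed as log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 6 libraries of a table (10739 in the RYGB table, 10801 in the sham table). Differences are on that scale, which understates the change of genes of low level. Groups were compared with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, an intensity trend and robust variances, Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used. The 49 preset gene lists of pathways and cell types (729 genes, 668 found, 10 of these by a synonym) were tested with camera from limma at a preset inter-gene correlation of 0.01, which compares a list with the remaining genes, for the 43 lists with at least 4 measured genes; p-values were adjusted over the lists within a comparison. The other 6 lists had fewer measured genes and were left out. Of the 10 synonyms, 3 led to another gene: Psme3 in gluconeogenesis, Itgad in the macrophage and dendritic list, and Mtnr1b, below the level filter, among the metal handling genes. The lists were also tested without them, which changed no list call in either table or with the block. A list's place among 10000 random lists of like level was used to describe single libraries.

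In the RYGB table same-numbered libraries deviated together from their group means, with correlations across genes of 0.85, 0.76 and 0.77. Libraries of other numbers gave -0.13 to -0.59, in part by construction, since deviations from a group mean cancel within the group. In the sham table FDG-increased replicate 3 and sham replicate 2, of unlike numbers, gave 0.66. Libraries of pairs 1 and 2 also shared a lane, which cannot be told apart from the pairing there. The pairing is taken from the numbers in the labels, which do not say what the numbers share. Values with the replicate number as a block are therefore given beside those without it where the call differs. Labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples. Lane numbers in the labels were 7 for the 3 sham libraries, 7, 4 and 5 for FDG-decreased, and 7, 4 and 4 for FDG-increased.

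The genes named were, per comparison, the 8 highest and 8 lowest log2 differences among genes past the threshold at or above the median level, up to 3 genes with the smallest p from each list with at least 3 genes past it, and a fixed panel: Slc2a1, Slc2a2, Slc5a1, Hk1, Hk2, Pkm, Ldha, Areg, Egfr, Gcg, Pyy, Slc10a2, Fabp6 and Nr1h4. Members of the lists are also named with their values. A result that the rule would name is not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Genes named outside the rule and the lists were chosen after their values were seen: Hspb1, Cryab, Bag3, Hspa1a, Hspa1b, Dnajb1, Sik1, Hoxb9 and Vdr.

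Alternatives tried were a pseudocount of 0.1, no filter on low values, the replicate block, lane, other thresholds, leaving out each library, libraries shifted to the same median, quantile normalization, and for the lists an estimated or a higher correlation, ranks, fry, genes at or above the median level, unshared members, no wrong synonyms and the fit without sham replicate 1. The test of the enterocyte share in the closing section replaced a test on Fabp6 alone, and that of position replaced a difference of sham replicates 1 and 3. The pipeline was tested on simulated data with 200 changed genes in each of 5 draws, with residuals independent across genes. In the sham table (10801 genes), 12.4%, 66%, 89.6% and 95.2% of genes changed by 1, 2, 3 and 4 on the log2 scale were called, and 0.0623% of unchanged genes. In the RYGB table (10739 genes) the shares were 2.8%, 52.8%, 74% and 88% without the block, with 0% of unchanged genes, and 48.8%, 86.8%, 96% and 97.6% with it, with 0.0114% of unchanged genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.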

Results

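Total RNA was measured in the ileum, the last part of the small intestine, of Otsuka Long-Evans Tokushima fatty rats 1 month after Roux-en-Y gastric bypass (RYGB) or a sham operation. The labels divide the RYGB samples by FDG, taken as the radioactive glucose analogue fluorodeoxyglucose, into samples with FDG decreased and samples with FDG increased. Each of the 3 groups has 3 replicates. Values are FPKM, and the sum of FPKM per library lay between 465697 and 864511, with 10332 to 10892 genes at 1 FPKM or more. The series asks what RYGB does to the small intestine. Its tables set FDG-increased RYGB ileum against sham ileum, and FDG-decreased against FDG-increased RYGB ileum. A pair of FDG-increased libraries is in both tables, which were scaled separately. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples. Log2 differences are on the log2(FPKM + 1) scale, which understates genes of low level.

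Atf3, Nr4a1, Fosb and S100g rose in RYGB ileum with FDG increased against sham ileum. Atf3, a transcription factor induced by cell stress, stood at 108.6 ± 36.5 FPKM (SD, n = 3) against 7.03 ± 2.95 in sham ileum (SD, n = 3). Nr4a1, a nuclear receptor induced within minutes of a stimulus, stood at 48.2 ± 8.37 against 4.40 ± 2.56 FPKM (SD, n = 3 each), and Fosb, a subunit of the transcription factor AP-1, at 23.0 ± 10.3 against 1.18 ± 0.763 FPKM (SD, n = 3 each). S100g, the calcium-binding protein calbindin of absorptive cells, stood at 604 ± 240 against 43.2 ± 19.7 FPKM (SD, n = 3 each). These 4 genes rose by 3.80 (SE 0.378), 3.29 (SE 0.378), 3.44 (SE 0.373) and 3.79 (SE 0.431) on the log2 scale, in that order. For each of them limma gave a Benjamini-Hochberg adjusted p of 0.0306. In this comparison all 3 FDG-increased libraries lay above all 3 sham libraries, and chance gives groups that do not overlap, in either direction, for 10% of genes. The FDG-increased library found only in the other comparison was not among them. On its own scale it held 24.4 FPKM of Atf3, 5.99 of Nr4a1, 10.5 of Fosb and 84.3 of S100g. Its Nr4a1 lay inside the sham range of 1.855 to 6.97 FPKM, and the other genes lay above all sham libraries. These 4 were the only genes of 10801 past the threshold of 0.05. By limma 847 genes had an unadjusted p under 0.05, 664 of them higher and 183 lower in FDG-increased ileum. The median over all genes was 0.13 higher in FDG-increased ileum. With the libraries shifted to the same median, 3 genes were called, and the genes at an unadjusted p under 0.05 divided into 518 higher and 377 lower. Quantile normalization called 0 genes with limma, with 479 higher and 333 lower at an unadjusted p under 0.05. With a pseudocount of 0.1 limma called 1 gene, and with no filter on low values 0, where 1055 had an unadjusted p under 0.05.

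The 4 calls depended on single libraries. With limma and Benjamini-Hochberg adjustment, 0 genes were called without FDG-increased replicate 1, without FDG-increased replicate 2 or without sham replicate 2. Without sham replicate 1 the count was 1, a gene lower in FDG-increased ileum and none of the 4. Without FDG-increased replicate 3 it was 13, with all 4 kept, and without sham replicate 3 it was 7, with 3 of the 4 kept. Each of the 4 stayed higher in FDG-increased ileum in all of these fits, as it had to, since the groups did not overlap. Limma adjusted p after Benjamini-Hochberg ranged from 0.0114 to 0.0994 for Atf3 and from 0.0155 to 0.161 for Nr4a1. By the same adjustment of limma it ranged from 0.0155 to 0.178 for Fosb and from 0.0155 to 0.169 for S100g. The sham libraries all came from lane 7, and with lane 7 libraries alone, 1 FDG-increased against 3 sham, 3 genes were called, Atf3 and Fosb among them. That fit takes the lone library to vary like the sham libraries.

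Immediate-early genes, which cells switch on within minutes of a stimulus, lay higher as a group. Of 19 measured, 18 were higher in FDG-increased ileum, with a median log2 difference of 1.58. Of these, 3 passed over all genes and 18 when adjusted over the list alone. Fos, another subunit of AP-1, stood at 247 ± 137 against 34.1 ± 21.2 FPKM, and Egr1, an early transcription factor with zinc fingers, at 70.5 ± 29.6 against 9.89 ± 2.84 FPKM (SD, n = 3 each). In the FDG-increased library outside this comparison, Fos stood at 30.3 FPKM, inside the sham range of 16.0 to 57.3 FPKM. Egr1 stood there at 18.7 FPKM, above all sham libraries. The mean log2 value of the list was 4.22 in that library, against 3.77, 3.47 and 3.95 in the sham libraries. The list test, camera, gave a Benjamini-Hochberg adjusted p of 5.69e-22, and adjusted p = 0.337 with an estimated correlation. Cytokines and chemokines of inflammation went the same way: 9 of 10 were higher, with a median of 1.08, 0 over all genes by limma and 5 adjusted over the list alone. Ptgs2, which makes prostaglandins, stood at 33.2 ± 10.1 against 3.97 ± 2.75 FPKM, and Ccl2, which attracts monocytes, at 62.9 ± 44.1 against 8.47 ± 3.64 FPKM (SD, n = 3 each). For this list camera gave a Benjamini-Hochberg adjusted p of 8.69e-05, and adjusted p = 0.480 with an estimated correlation. In the family of epidermal growth factor (EGF) ligands and receptors, 9 of 12 members were higher, with a median of 0.40, 0 over all genes by limma and 3 adjusted over the list alone. The ligands differed among themselves. Ereg stood at 60.5 ± 29.6 against 5.6 ± 4.0 FPKM and Hbegf at 24.4 ± 7.59 against 3.84 ± 1.62 FPKM (SD, n = 3 each). In the FDG-increased library outside this comparison, Ereg stood at 9.08 FPKM, inside the sham range of 2.61 to 10.15 FPKM. Hbegf stood there at 11.4 FPKM, above all sham libraries. Btc and Tgfa differed between FDG-increased and sham ileum by -0.20 and 0.04 on the log2 scale. The EGF list had a camera and Benjamini-Hochberg adjusted p of 0.00401, and adjusted p = 0.489 with an estimated correlation. With ranks its call was lost (adjusted p = 0.082 by camera with Benjamini-Hochberg).

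Genes of several immune and secretory cell types were also higher as groups in the FDG-increased libraries of this comparison, with few single members past any test. In the FDG-increased library outside it, 17 T and NK cell markers had a mean log2 value of 1.22. The 16 measured in the sham libraries had 2.69, 1.93 and 2.8. Macrophage and dendritic markers had 2.38 against 4.1, 3.59 and 3.94, and mast cell and eosinophil markers 1.89 against 3.41, 2.52 and 2.48. These immune means lay below all sham libraries, while Paneth markers lay above, at 10.95 against 9.41, 9.86 and 9.77. B and plasma cell markers, 5 of 7 higher (median 0.27), were not called (camera with Benjamini-Hochberg, adjusted p = 0.333). The T and NK cell markers were higher for 15 of 16 (median 0.86), and 1 passed adjusted over the list alone. Cd7, a surface protein of T cells, stood at 52.3 ± 14.9 against 16.7 ± 6.69 FPKM (SD, n = 3 each). These markers had a camera and Benjamini-Hochberg adjusted p of 2.05e-06, and adjusted p = 0.480 with an estimated correlation. Macrophage and dendritic markers were higher for 11 of 14 (median 0.80, 3 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.000428, and adjusted p = 0.489 with an estimated correlation. Their members Csf1r, the receptor for a macrophage growth factor, and Cd68, a protein of lysosomes, differed by 1.30 and 1.11 on the log2 scale. The list also held Itgad, brought in by a wrong synonym, and without it 10 of 13 were higher (median 0.97), with camera and Benjamini-Hochberg adjusted p = 0.000404, and adjusted p = 0.489 with an estimated correlation. Mast cell and eosinophil markers were higher for 7 of 7 (median 0.93, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.00647, and adjusted p = 0.497 with an estimated correlation. Paneth cells, which secrete antimicrobial proteins at the crypt base, had 9 of 9 markers higher (median 0.97, 0 adjusted over the list alone). Their adjusted p by camera with Benjamini-Hochberg was 0.000396, and adjusted p = 0.480 with an estimated correlation. The antimicrobial peptides and lectins, 14 of 15 higher (median 0.92, 0 adjusted over the list alone), included Reg3g, a lectin that binds bacteria, at 3254 ± 954 against 652.5 ± 648 FPKM, and Defa8, an alpha-defensin, at 8292 ± 1922 against 3502 ± 1468 FPKM (SD, n = 3 each). For these, camera with Benjamini-Hochberg gave an adjusted p of 0.00043, and adjusted p = 0.489 with an estimated correlation.

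The interferon response was higher for 19 of 23 genes (median 0.41, 2 adjusted over the list alone), among them Irf7 by 1.26 and Oas1a by 1.48 on the log2 scale. That list had a camera and Benjamini-Hochberg adjusted p of 0.00504, and adjusted p = 0.497 with an estimated correlation. Its mean log2 value in the FDG-increased library outside this comparison was 2.24 over 22 genes. The sham libraries had 3, 2.74 and 3.25 over 23 genes. Iron, zinc and metal handling genes were higher for 9 of 11 (median 0.64, 3 adjusted over the list alone), led by Slc30a10, a manganese exporter, at 33.8 ± 8.89 against 6.42 ± 4.55 FPKM (SD, n = 3 each). This list had a camera and Benjamini-Hochberg adjusted p = 0.00301, and adjusted p = 0.480 with an estimated correlation. Goblet cells, the source of mucus, had 8 of 9 markers higher (median 0.62, 2 adjusted over the list alone), with Zg16, a lectin of mucus, at 3271 ± 337 against 1288 ± 699 FPKM (SD, n = 3 each). Their camera and Benjamini-Hochberg adjusted p was 0.0456, and adjusted p = 0.662 with an estimated correlation. In the FDG-increased library outside this comparison the goblet mean was 8.35, above 8.01, 7.31 and 6.63 in the sham libraries. Enteroendocrine markers were higher for 11 of 15 (median 0.55), with 3 higher and 1 lower adjusted over the list alone. Nts, the gut hormone neurotensin, stood at 165.3 ± 1.67 against 62.6 ± 4.87 FPKM (SD, n = 3 each), and the list had a camera and Benjamini-Hochberg adjusted p of 0.0346, and adjusted p = 0.480 with an estimated correlation. All 18 ribosomal protein genes were higher (median 0.45, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.00584, but with quantile normalization the direction flipped to lower with adjusted p = 0.238, and adjusted p = 0.579 with an estimated correlation.

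Groups that lay lower in FDG-increased ileum were the cell cycle, adipocyte, neuron and glia, endothelial and extracellular matrix lists, and the erythroid and proximal lists taken up with sham replicate 1. Smooth muscle markers, 6 of 12 lower, and fibroblast markers, 5 of 9 lower, were not called (camera with Benjamini-Hochberg, adjusted p = 0.190 and 0.233), though they were called lower among genes at or above the median level (adjusted p = 0.0455 and 0.00496). Of 24 cell cycle genes 21 were lower, with a median of -0.29 and 0 adjusted over the list alone. Among them Rrm2, a subunit of ribonucleotide reductase, stood at 19.9 ± 5.51 against 36.0 ± 8.66 FPKM (SD, n = 3 each). Camera with Benjamini-Hochberg gave an adjusted p of 3.99e-07, and adjusted p = 0.480 with an estimated correlation. Adipocyte markers were lower for 8 of 9 (median -0.94, 0 adjusted over the list alone), and Cidec, a protein of fat droplets, stood at 9.83 ± 1.78 against 22.4 ± 10.5 FPKM (SD, n = 3 each). Their camera and Benjamini-Hochberg adjusted p was 8.69e-05, and adjusted p = 0.480 with an estimated correlation. Adipoq, the fat cell hormone adiponectin, varied among the sham libraries themselves from 0.14 to 15.7 and 71.3 FPKM. Neuron and glia markers were lower for 8 of 11 (median -0.27) and endothelial markers for 9 of 12 (median -0.16), with camera and Benjamini-Hochberg adjusted p = 0.0181 for each and 0 members adjusted over the list alone. With an estimated correlation the neuron and glia list had adjusted p = 0.480 and the endothelial list adjusted p = 0.566. Extracellular matrix genes were lower for 10 of 16 (median -0.06, 0 adjusted over the list alone), with Col1a1, a chain of collagen, at 18.9 ± 5.46 against 36.1 ± 6.81 FPKM (SD, n = 3 each). That list had a camera and Benjamini-Hochberg adjusted p of 0.0199, and adjusted p = 0.480 with an estimated correlation. In all, 22 of 43 lists passed, 15 higher and 7 lower, and 0 of 43 passed with an estimated correlation or with fry, while limma had 847 single genes at an unadjusted p under 0.05. With quantile normalization 19 lists passed, 16 of them shared. The Paneth, goblet, neuron and glia, endothelial and proximal calls were then lost, with camera and Benjamini-Hochberg adjusted p of 0.0516, 0.341, 0.0597, 0.0543 and 0.161, beside the ribosomal call. In the same setting glycolysis, smooth muscle and the nuclear genes of oxidative phosphorylation were called lower with camera and Benjamini-Hochberg adjusted p of 0.0134, 0.00879 and 0.0159. Other settings of camera with Benjamini-Hochberg ended calls too. With ranks, goblet, enteroendocrine and proximal genes had adjusted p of 0.0672, 0.0798 and 0.190. At a correlation of 0.05, the extracellular matrix, goblet, enteroendocrine, neuron and glia, endothelial and proximal lists had camera and Benjamini-Hochberg adjusted p of 0.0746, 0.0948, 0.0951, 0.0558, 0.0558 and 0.0746. Among genes at or above the median level the interferon response was not called (camera with Benjamini-Hochberg, adjusted p = 0.445), and the mast cell and eosinophil, neuron and glia, endothelial and erythroid lists had too few genes for the test. Without genes shared between lists the antimicrobial genes were not called (camera with Benjamini-Hochberg, adjusted p = 0.118), and the Paneth and proximal lists had too few genes.

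Genes of bile acid uptake and of the upper intestine set sham replicate 1 apart from the other sham libraries. Fabp6, the ileal bile acid binding protein, stood at 22.6 FPKM there and at 8375 and 11350 FPKM in sham replicates 2 and 3. Slc10a2, the ileal bile acid uptake transporter, stood at 2.6 against 67.3 and 119.9 FPKM. Lct, the lactase of the upper intestine, stood at 253 against 8.6 and 0.317 FPKM, and Gip, a hormone of the upper intestine, at 81.2 against 10.7 and 3.70 FPKM. Gata4, of the proximal list, stood at 59.8 against 9.82 and 0.0853 FPKM. The proximal list means were 4.98, 3.23 and 2.32 in sham replicates 1 to 3. Sham replicate 2 thus lay between the others, and leaving out sham replicate 1 does not remove that difference. Beside these values, all 9 bile acid genes were higher in FDG-increased ileum (median 0.99, 1 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.00504, and adjusted p = 0.480 with an estimated correlation. Fabp6 itself stood at 19470 ± 3257 against 6582 ± 5872 FPKM and Slc10a2 at 289 ± 255 against 63.3 ± 58.7 FPKM (SD, n = 3 each). Neither passed (limma with Benjamini-Hochberg, adjusted p = 0.743 for Fabp6 and 0.644 for Slc10a2). Genes of the proximal small intestine and stomach divided into 3 higher and 4 lower of 7, with a median of -0.14 and a mean of -1.13, and had a camera and Benjamini-Hochberg adjusted p of 0.0396 as lower. Erythroid genes were lower for 5 of 5 (median -0.53), with camera and Benjamini-Hochberg adjusted p = 0.00283, and the MHC class II genes, which present antigen, were higher for 6 of 7 (median 1.16), with camera and Benjamini-Hochberg adjusted p = 0.0176. With an estimated correlation the proximal list had adjusted p = 0.480, the erythroid list adjusted p = 0.489 and the MHC class II list adjusted p = 0.533. Without sham replicate 1 these 3 lists were no longer called, with camera and Benjamini-Hochberg adjusted p of 0.167, 0.0605 and 0.0768. The bile acid list was still called there (camera with Benjamini-Hochberg, adjusted p = 0.0200). In the FDG-increased library outside this comparison the MHC class II mean was 4.08, below 5.81, 5.24 and 7.01 in the sham libraries.

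Further lists, not called with all libraries, were called without sham replicate 1, where Apoa4, an apolipoprotein of absorbed fat, stood at 1719 FPKM against 68.7 and 32.3 in the other sham libraries. With all libraries, fat absorption genes divided into 10 higher and 10 lower, with a median of 0.02, a mean of -0.15 and a camera test that leaned lower with a Benjamini-Hochberg adjusted p of 0.280. Without that library they were called higher with camera and Benjamini-Hochberg adjusted p = 0.00313, and adjusted p = 0.443 with an estimated correlation. With all libraries and genes at or above the median level alone they were called lower (camera with Benjamini-Hochberg, adjusted p = 0.0232), and over all genes they had adjusted p = 0.883 with an estimated correlation. Absorptive enterocyte markers (9 of 11 higher, median 0.54) went from a camera and Benjamini-Hochberg adjusted p of 0.237 to 4.50e-05 without it, and brush-border hydrolases (10 of 15 higher, median 0.82, 4 adjusted over the list alone) from 0.0569 to 0.00294. Without that library each of these lists had adjusted p = 0.443 with an estimated correlation. The hydrolases were also called with all libraries once genes shared with other lists were left out (camera with Benjamini-Hochberg, adjusted p = 0.0199). Xenobiotic metabolism (19 of 25 higher) went from 0.150 to 0.00391, the nuclear genes of oxidative phosphorylation (20 of 26 higher) from 0.721 to 0.00203 and fatty acid oxidation from 0.442 to 0.0176, by camera with Benjamini-Hochberg and as higher, though with quantile normalization of all libraries oxidative phosphorylation was called lower (adjusted p = 0.0159) and fatty acid oxidation leaned lower (adjusted p = 0.773). Without sham replicate 1 these 3 lists each had adjusted p = 0.458 with an estimated correlation. Intestinal stem cell markers (5 of 8 lower) went from a camera and Benjamini-Hochberg adjusted p of 0.112 to 0.0248 as lower, and adjusted p = 0.443 with an estimated correlation. In all, 26 lists were called without sham replicate 1, 19 of them among the 22 with all libraries, and 0 of 43 with an estimated correlation. The FDG-increased library outside this comparison had list means of 5.73 for fat absorption and 7.96 for enterocyte markers. Both lay below sham replicates 2 and 3, at 6.45 and 6.35 and at 8.43 and 8.81. The mean of oxidative phosphorylation lay above both, at 7.88 against 7.76 and 7.36.

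Of the genes of glucose uptake and use that were fixed in advance, no member passed in FDG-increased against sham ileum. Slc2a1, the glucose transporter of most cells, stood at 8.89 ± 1.20 against 6.55 ± 1.15 FPKM (SD, n = 3 each), a log2 difference of 0.39 (SE 0.238; limma with Benjamini-Hochberg, adjusted p = 0.739). Hk2, a hexokinase that traps glucose in the cell, stood at 27.2 ± 10.1 against 18.4 ± 6.15 FPKM (SD, n = 3 each; limma with Benjamini-Hochberg, adjusted p = 0.758). The log2 differences were -0.74 for Slc2a2, the glucose transporter of the enterocyte's base, 0.13 for Slc5a1, the sodium-coupled glucose transporter of the brush border, -0.15 for the hexokinase Hk1, -0.14 for the pyruvate kinase Pkm and -0.59 for the lactate dehydrogenase Ldha. Slc2a2 stood at 26.2 ± 21.4 against 96.9 ± 142 FPKM (SD, n = 3 each), and without sham replicate 1 its difference was 0.68. That library also turned the direction of Pkm, to 0.29 without it, and of Ldha, to 0.23. Slc5a1 turned to -0.38 with quantile normalization, -0.02 without FDG-increased replicate 3, -0.34 without sham replicate 2 and -0.28 without sham replicate 3. The glycolysis list divided into 12 higher and 12 lower and was not called (camera with Benjamini-Hochberg, adjusted p = 0.107). It was called lower with quantile normalization (adjusted p = 0.0134) and among genes at or above the median level (adjusted p = 0.0182). Over all genes without quantile normalization it had adjusted p = 0.770 with an estimated correlation. The glucose and fructose transport list divided into 5 and 5, with a median of 0.06, a mean of 0.03 and a test that leaned lower, and higher with quantile normalization (camera with Benjamini-Hochberg, adjusted p = 0.819 and 0.828). Areg, an EGF ligand, stood at 42.7 ± 27.1 against 3.55 ± 2.39 FPKM (SD, n = 3 each), a log2 difference of 3.24 (SE 0.571, limma with Benjamini-Hochberg, adjusted p = 0.162). The FDG-increased library outside this comparison held 2.72 FPKM of Areg, inside the sham range of 0.886 to 5.51 FPKM. Egfr, the receptor of Areg, differed by -0.04, or by 0.05 without FDG-increased replicate 1 and 0.02 without sham replicate 3. The hormone genes Gcg, which encodes glucagon-like peptides, and Pyy, peptide YY, stood at 282.9 ± 130.2 against 80.7 ± 24.9 and at 64.0 ± 30.2 against 14.7 ± 6.46 FPKM (SD, n = 3 each). Their limma adjusted p-values with Benjamini-Hochberg were 0.390 for Gcg and 0.268 for Pyy, at log2 differences of 1.74 and 2.06. Nr1h4, the bile acid receptor, stood at 87.3 ± 38.9 against 35.9 ± 13.8 FPKM (SD, n = 3 each) and was higher without passing (limma with Benjamini-Hochberg, adjusted p = 0.580).

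**Figure D1:**
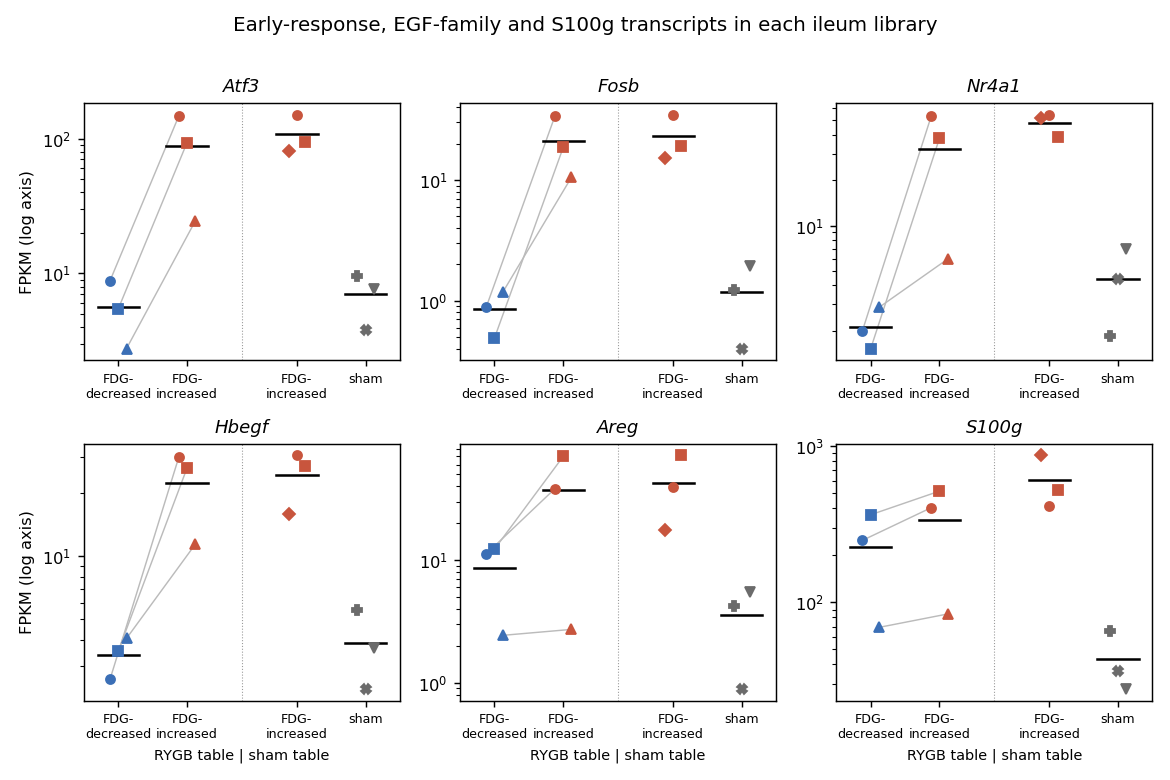
FPKM on a log axis of Atf3, Fosb, Nr4a1, Hbegf, Areg and S100g, 1 point per library and a black bar for the group mean, with the RYGB table left of the dotted line, where grey lines join equal replicate numbers, and the separately scaled sham table right of it, where the circle and the square mark the FDG-increased libraries also found in the RYGB table. Atf3 averaged 108.6 FPKM in FDG-increased and 7.03 in sham libraries, and 5.69 in FDG-decreased libraries.

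FDG-decreased RYGB ileum was set against FDG-increased RYGB ileum to ask how the RYGB samples that differ in FDG differ in their RNA. Without use of the replicate numbers limma called 0 of 10739 genes, with 110 at an unadjusted p under 0.05, 39 higher and 71 lower in FDG-decreased ileum. With the replicate number as a block, since same-numbered libraries deviated together, limma with Benjamini-Hochberg called 122 genes, 48 higher and 74 lower in FDG-decreased ileum. What the numbers share is not given. For FDG-increased against sham ileum, where the numbers share only a name, the block also raised the count, from 4 to 39 genes. Each of the 122 went the same way in 3 of 3 pairs, which a call from 3 pairs itself favours. Atf3 stood at 5.69 ± 3.03 FPKM in FDG-decreased and 88.0 ± 61.2 in FDG-increased ileum (SD, n = 3 each), and Fosb at 0.852 ± 0.344 against 21 ± 11.9 FPKM (SD, n = 3 each). With the block they fell by 3.51 (SE 0.227) and 3.44 (SE 0.329) on the log2 scale, with limma and Benjamini-Hochberg adjusted p of 0.000366 and 0.00736. Without the block the smallest limma adjusted p after Benjamini-Hochberg was 0.305, for Fosb and Ano6.

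Among the 48 genes called higher in FDG-decreased ileum with the block were Ano6, Asah2, Cyp2b1, Cubn, Tm4sf4 and Tm4sf5. Ano6, a channel and lipid scramblase of the cell membrane, stood at 71.7 ± 16.9 against 11.6 ± 2.85 FPKM (SD, n = 3 each), a rise of 2.53 (SE 0.189; limma with Benjamini-Hochberg, adjusted p = 0.000318). Asah2, a ceramidase of the brush border, stood at 39.1 ± 19.6 against 5.50 ± 4.89 FPKM, and Cyp2b1, a cytochrome of xenobiotic metabolism, at 40.2 ± 29.1 against 5.77 ± 5.17 FPKM (SD, n = 3 each). Cubn, a receptor for the uptake of vitamin B12 bound to intrinsic factor, stood at 75.8 ± 53.3 against 21.8 ± 17.8 FPKM (SD, n = 3 each). The membrane proteins Tm4sf4 and Tm4sf5 stood at 258.7 ± 43.2 against 108.6 ± 47.5 and at 186.5 ± 13.0 against 78.2 ± 7.22 FPKM (SD, n = 3 each). Limma with the block and Benjamini-Hochberg gave adjusted p of 0.00555 for Asah2, 0.00422 for Cyp2b1, 0.00555 for Cubn, 0.0141 for Tm4sf4 and 0.00144 for Tm4sf5, with rises of 2.80, 2.63, 2.03, 1.32 and 1.25, each in 3 of 3 pairs.

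The 74 genes that fell with the block included Rgs1, Egr1, Gem, Trib1, Tppp and Zfand2a. Rgs1, which dampens chemokine signals in lymphocytes, stood at 17.7 ± 12 against 82.9 ± 66.3 FPKM and Egr1 at 11.6 ± 8.14 against 48.8 ± 37.9 (SD, n = 3 each). Gem, a small GTPase, stood at 10.2 ± 3.80 against 45.3 ± 33.5 FPKM, and Trib1, a pseudokinase, at 16.5 ± 4.82 against 60.1 ± 24.6 FPKM (SD, n = 3 each). Tppp, a protein of microtubules, stood at 7.66 ± 3.57 against 27.2 ± 8.75 FPKM and Zfand2a, induced by damaged proteins, at 25.2 ± 11.1 against 76.8 ± 16.4 (SD, n = 3 each). With limma, the block and Benjamini-Hochberg, Rgs1 fell by 2.03 (adjusted p = 0.000318) and Egr1 by 1.94 (adjusted p = 0.000318), each in 3 of 3 pairs. In the same fit of limma with Benjamini-Hochberg, the log2 differences were -1.82 for Gem (adjusted p = 0.0271), -1.75 for Trib1 (adjusted p = 0.000736), -1.73 for Tppp (adjusted p = 0.000589) and -1.66 for Zfand2a (adjusted p = 0.00144). The block count rests on the pairs: with limma and Benjamini-Hochberg it was 35 without pair 1, 415 without pair 2 and 346 without pair 3. Of the 122 genes, 26, 116 and 121 were called again, in that order. All 122 kept their sign, which their agreement in 3 of 3 pairs fixed beforehand. Without the block and without FDG-decreased replicate 1, 1 gene was called.

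As a group, all 19 immediate-early genes were lower in FDG-decreased ileum, and each of the 19 was lower in 3 of 3 pairs. Their median log2 difference was -1.02. By limma 0 passed over all genes and 5 adjusted over the list alone, and with the block 12 passed over all genes and 18 adjusted over the list alone. Camera with Benjamini-Hochberg gave an adjusted p of 2.92e-45, and adjusted p = 0.209 with an estimated correlation. The EGF family was lower for 9 of 12 (median -0.20, 2 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 7.18e-07, and adjusted p = 0.389 with an estimated correlation. Its ligand Hbegf stood at 3.39 ± 0.744 against 22.5 ± 9.76 FPKM, and Errfi1, an inhibitor of EGF receptors, at 21.2 ± 2.80 against 48.8 ± 5.01 FPKM (SD, n = 3 each). With the block and Benjamini-Hochberg they fell by 2.33 (limma adjusted p = 0.0354) and 1.17 (limma adjusted p = 0.0045). Inflammatory cytokines and chemokines were lower for 10 of 10 (median -0.52, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 1.25e-06, and adjusted p = 0.389 with an estimated correlation. Antimicrobial peptides and lectins were lower for 12 of 14 (median -0.25, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 3.96e-05, and adjusted p = 0.389 with an estimated correlation. Reg3g stood at 2402 ± 590 against 4609 ± 1532 FPKM (SD, n = 3 each) and fell with the block by 0.92 (limma with Benjamini-Hochberg, adjusted p = 0.0104). Genes of the hypoxia response were lower for 10 of 12 (median -0.35, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.000403, and adjusted p = 0.273 with an estimated correlation. Cholesterol synthesis genes, Hmgcs1 by -0.68 among them, were lower for 19 of 21 (median -0.24, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 7.18e-07, and adjusted p = 0.389 with an estimated correlation. Goblet and Paneth markers were lower for 8 of 9 each (medians -0.31 and -0.20, 0 adjusted over the list alone in each), with camera and Benjamini-Hochberg adjusted p of 0.0157 and 0.0112. With an estimated correlation goblet had adjusted p = 0.389 and Paneth adjusted p = 0.749. Smooth muscle genes were lower for 7 of 12 (median -0.16, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.0334, and adjusted p = 0.856 with an estimated correlation. Quantile normalization ended the goblet, Paneth and smooth muscle calls (camera with Benjamini-Hochberg, adjusted p = 0.0947, 0.139 and 0.183). With the block, members lower when adjusted over the list alone numbered 3 in the EGF family, 2 of the inflammatory, 5 of the antimicrobial, 2 of the hypoxia, 6 of the cholesterol, 1 of the goblet, 2 of the smooth muscle and 0 of the Paneth genes. Over all genes limma with the block called 2 lower in the EGF family and 1 each of the antimicrobial, hypoxia and cholesterol genes.

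Genes of fat absorption and of the absorptive epithelium were higher in FDG-decreased ileum. Of 20 fat absorption genes 19 were higher, 17 of them in 3 of 3 pairs, with a median of 0.70. By limma 0 passed adjusted over the list alone without the block, and 4 over all genes and 16 adjusted over the list alone with it. Camera with Benjamini-Hochberg gave an adjusted p of 3.38e-11, and adjusted p = 0.389 with an estimated correlation. Apoc3, an apolipoprotein of chylomicrons, stood at 41.3 ± 36.7 against 15.6 ± 11.8 FPKM (SD, n = 3 each), and with limma, the block and Benjamini-Hochberg it rose by 1.26 (adjusted p = 0.00422), the fatty acid receptor Cd36 by 0.96 (adjusted p = 0.0056) and Mogat2, which rebuilds triglycerides, by 0.88 (adjusted p = 0.0183). Brush-border hydrolases were higher for 11 of 16 (median 0.44, 3 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 3.76e-05, and adjusted p = 0.749 with an estimated correlation. Among them Ace, the enzyme that makes angiotensin II, stood at 86.8 ± 79.9 against 33.9 ± 24.1 FPKM, Treh, which splits trehalose, at 6.18 ± 2.34 against 1.82 ± 0.643, and Lct at 4.72 ± 3.52 against 0.444 ± 0.286 FPKM (SD, n = 3 each). With limma, the block and Benjamini-Hochberg, Ace rose by 1.14 (adjusted p = 0.00758), Treh by 1.33 (adjusted p = 0.00555) and Lct by 1.8 (adjusted p = 0.0191). Genes of the proximal small intestine and stomach were higher for 5 of 7 (median 0.33, 3 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 2.38e-06, and adjusted p = 0.209 with an estimated correlation. Gip stood at 7.99 ± 4.50 against 1.09 ± 0.999 FPKM (SD, n = 3 each) and rose with the block by 2.10 (limma with Benjamini-Hochberg, adjusted p = 0.000318). Enterocyte markers were higher for 9 of 11 (median 0.54, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.00373, and adjusted p = 0.813 with an estimated correlation. With the block, 8 enterocyte markers were higher and 1 lower adjusted over the list alone and 1 was higher over all genes. By the same fit 8 brush-border hydrolases were higher adjusted over the list alone and 4 over all genes, and 2 proximal genes by either count.

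Xenobiotic metabolism genes were higher in FDG-decreased ileum for 19 of 24 (median 0.27, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.00116, and adjusted p = 0.856 with an estimated correlation. Among them the cytochromes Cyp2j4 and Cyp3a18 rose with the block by 0.86 and 0.81 (limma with Benjamini-Hochberg, adjusted p = 0.0141 and 0.0271), each in 3 of 3 pairs. Fatty acid oxidation genes were higher for 19 of 21 (median 0.19, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.0112, and adjusted p = 0.856 with an estimated correlation. Cell cycle genes were higher for 21 of 24 (median 0.22, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p = 0.000455, and adjusted p = 0.767 with an estimated correlation. B and plasma cell markers were higher for 9 of 9 (median 0.34, 0 adjusted over the list alone) and tuft cell markers for 6 of 7 (median 0.35, 0 adjusted over the list alone), with camera and Benjamini-Hochberg adjusted p of 0.0048 and 0.0112. With an estimated correlation B and plasma had adjusted p = 0.819 and tuft adjusted p = 0.749. With the block, 6 xenobiotic genes were higher and 1 lower adjusted over the list alone and 3 were higher over all genes, and 1 fatty acid oxidation gene was higher by either count. The cell cycle, B and plasma and tuft lists had 0 members past either count with the block by limma, in which 1022 genes had an unadjusted p under 0.05. In all, 18 of 43 lists passed, 9 higher and 9 lower, and 0 of 43 with an estimated correlation or with fry, while limma had 110 single genes at an unadjusted p under 0.05. The block called 23 lists, and 5 of them were not called without it at the preset settings: gluconeogenesis (8 of 12 higher), MHC class II (7 of 7 lower), erythroid (5 of 5 higher), glucose and fructose transport (8 of 10 higher) and bile acid handling (6 of 9 lower). Their camera and Benjamini-Hochberg adjusted p-values went from 0.152 to 0.00913, 0.159 to 0.000127, 0.162 to 0.0313, 0.171 to 0.0231 and 0.171 to 0.0309. With the block and an estimated correlation these 5 had adjusted p = 0.514, adjusted p = 0.443, adjusted p = 0.615, adjusted p = 0.443 and adjusted p = 0.498. The gluconeogenesis list held Psme3, a regulator of the proteasome brought in by a wrong synonym. Without it 8 of 11 were higher, with camera and Benjamini-Hochberg adjusted p of 0.0748 without the block and 0.00304 with it, and adjusted p = 0.468 with the block and an estimated correlation. Without the block, gluconeogenesis and erythroid genes were called with quantile normalization (camera with Benjamini-Hochberg, adjusted p = 0.034 and 0.045), and MHC class II and ribosomal protein genes with ranks, as lower (adjusted p = 0.019 and 0.0305). Glucose and fructose transport was called without the block among genes at or above the median level and without genes shared between lists (camera with Benjamini-Hochberg, adjusted p = 0.0132 and 0.0385). With an estimated correlation and without the block, gluconeogenesis had adjusted p = 0.856, erythroid adjusted p = 0.859, MHC class II adjusted p = 0.884, ribosomal proteins adjusted p = 0.966 and glucose and fructose transport adjusted p = 0.749. Other settings of camera ended calls. Ranks ended those of the brush-border hydrolases and the proximal genes (camera with Benjamini-Hochberg, adjusted p = 0.0569 and 0.0859), and a correlation of 0.05 those of fatty acid oxidation and smooth muscle (adjusted p = 0.065 and 0.0896). Among genes at or above the median level the hydrolases, the hypoxia response and smooth muscle were not called (camera with Benjamini-Hochberg, adjusted p = 0.0982, 0.0552 and 0.0856), and the tuft, B and plasma and proximal lists had too few genes for the test. Without genes shared between lists the enterocyte, Paneth and proximal lists had too few.

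In the fixed panel, Hk2 fell with the block by 1.04 (SE 0.157; limma with Benjamini-Hochberg, adjusted p = 0.0111), at 17.5 ± 5.61 in FDG-decreased against 38.1 ± 15.7 FPKM in FDG-increased ileum (SD, n = 3 each) and lower in 3 of 3 pairs. Slc2a1 stood at 7.35 ± 2.72 against 10.1 ± 1.33 FPKM (SD, n = 3 each), lower in 3 of 3 pairs by -0.46 (block SE 0.164; limma with Benjamini-Hochberg, adjusted p = 0.346 with the block). Slc5a4, a relative of the sodium-coupled glucose transporter, rose with the block by 1.85 (limma with Benjamini-Hochberg, adjusted p = 0.0206), and Pdk4, a kinase that shuts pyruvate out of oxidation, by 1.10 (limma with Benjamini-Hochberg, adjusted p = 0.0413). Slc2a2 stood at 57.4 ± 47.7 against 19.6 ± 26.2 FPKM (SD, n = 3 each; limma with Benjamini-Hochberg, adjusted p = 0.437 with the block). The log2 differences were 0.43 for Slc5a1, 0.11 for Hk1, 0.06 for Pkm, 0.25 for Ldha and -0.10 for Egfr. Without FDG-increased replicate 3, Slc5a1 and Pkm turned to -0.22 each, and without FDG-decreased replicate 1, Pkm turned to -0.05 and Egfr to 0.09. The glycolysis list, with 17 of 24 higher, was called neither without the block (camera with Benjamini-Hochberg, adjusted p = 0.691) nor with it (adjusted p = 0.357). Areg stood at 8.64 ± 5.41 against 37.0 ± 33.7 FPKM (SD, n = 3 each), lower in 3 of 3 pairs by -1.41 (limma with Benjamini-Hochberg, adjusted p = 0.522 with the block). Fabp6 stood at 12890 ± 6583 against 16080 ± 7930 FPKM (SD, n = 3 each), lower in 3 of 3 pairs by -0.34, and by 0 with quantile normalization (limma with Benjamini-Hochberg, adjusted p = 0.437 with the block). The differences were -0.53 for Gcg, -0.30 for Pyy, -1.04 for Slc10a2 and -0.59 for Nr1h4, with limma adjusted p with the block and Benjamini-Hochberg of 0.110, 0.612, 0.643 and 0.0922. Without FDG-decreased replicate 3, Pyy, Slc10a2 and Fabp6 turned to 0.28, 0.03 and 0.20, and Pyy turned to 0.21 without FDG-increased replicate 1.

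**Figure D2:**
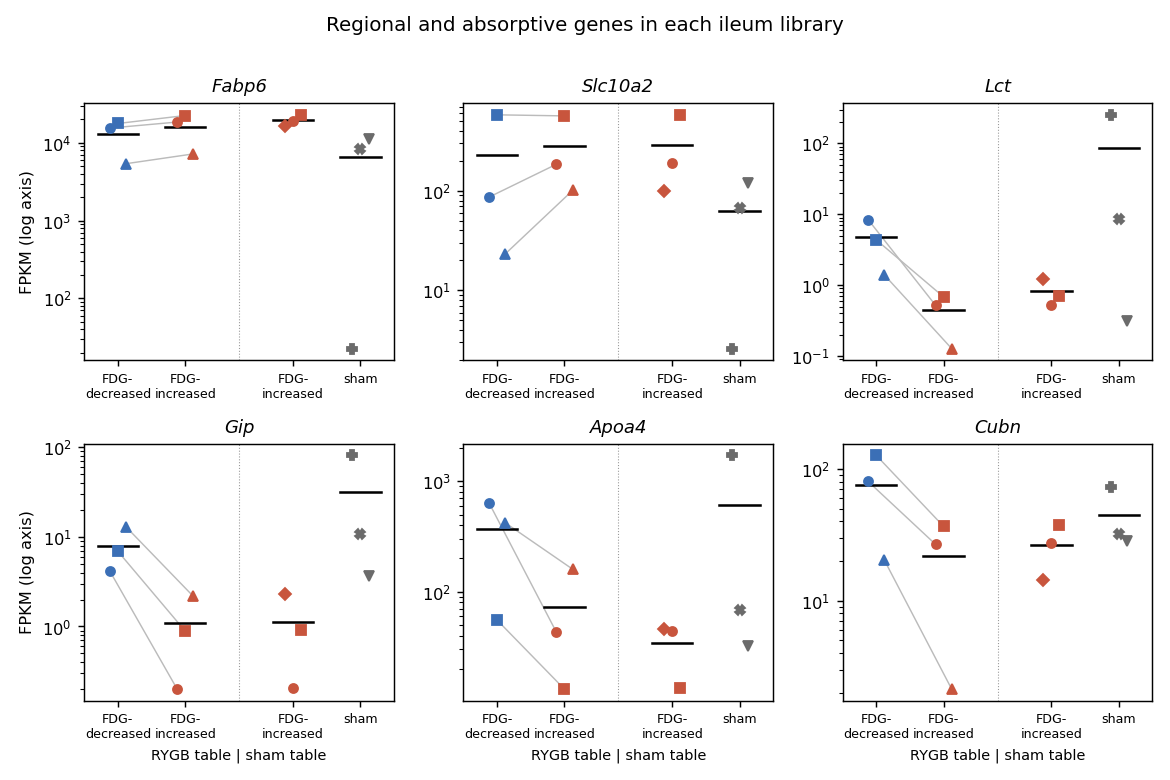
FPKM on a log axis of Fabp6, Slc10a2, Lct, Gip, Apoa4 and Cubn, 1 point per library and a black bar for the group mean, with the RYGB table left of the dotted line, where grey lines join equal replicate numbers, and the separately scaled sham table right of it. Sham replicate 1 (plus sign) stands apart, with Fabp6 at 22.6 FPKM against 8375 and 11350 in the other sham libraries and Lct at 253 against 8.6 and 0.317.

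**Figure D3:**
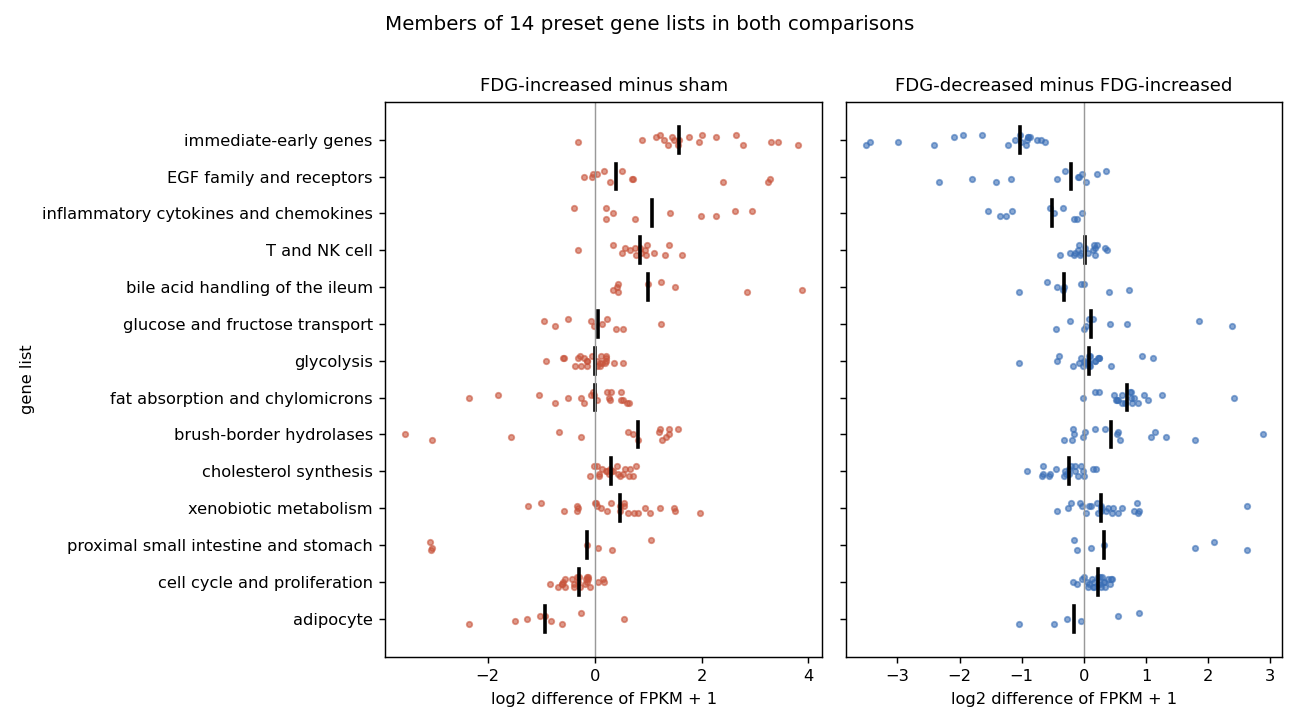
Log2 differences of FPKM + 1 for the measured genes of 14 preset lists, 1 point per gene and a black bar for the list median, for FDG-increased minus sham on the left and FDG-decreased minus FDG-increased on the right. The immediate-early genes have medians of 1.58 and -1.02, and the fat absorption genes of 0.02 and 0.70.

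In FDG-decreased RYGB ileum, S100g was 2.19 higher than in sham ileum on the log2 scale and adipocyte markers had a median of -1.08, while the median of 17 immediate-early genes was -0.01. The groups are in separately scaled tables, joined through the shared libraries with the factor 1.0217, so these are values with no test. With 1 library left out, S100g ranged from 1.71 to 2.90, and the immediate-early median from -0.34 without FDG-decreased replicate 1 to 0.29 without FDG-decreased replicate 3. Among the early genes Atf3 differed by -0.27, but by -0.60 without FDG-decreased replicate 1 or sham replicate 2, by -0.03 without sham replicate 1 and by 0.09 without FDG-decreased replicate 3. Fos differed by -0.76, from -1.26 without FDG-decreased replicate 1 to -0.31 without sham replicate 1, and Nr4a1 by -0.67, from -1.07 without sham replicate 1 to -0.33 without sham replicate 3. Fosb differed by -0.18, from -0.47 without sham replicate 2 to -0.03 without FDG-decreased replicate 2, and fell under the level filter without FDG-decreased replicate 3, sham replicate 1 or sham replicate 3. In all, 1 of the 17 was lower by 1 or more, 0 to 3 with 1 library left out. Fabp6 and Slc10a2 were 3.16 and 1.82 higher, but 0.26 and 0.27 higher without sham replicate 1. Slc10a2 was also 0.60 higher without FDG-decreased replicate 2, 2.90 without FDG-decreased replicate 3 and 2.80 without sham replicate 3. The gut hormone genes Pyy and Gcg were 1.44 and 1.09 higher, with ranges of 0.87 to 2.03 and 0.67 to 1.47 when 1 library was left out, the lowest without FDG-decreased replicate 1 for Pyy and replicate 2 for Gcg. Slc2a1 differed by 0.14, from -0.12 without FDG-decreased replicate 3 to 0.31 without FDG-decreased replicate 2. Hk2 differed by -0.03, and its direction turned to 0.06, 0.11 and 0.21 without FDG-decreased replicate 1, FDG-decreased replicate 2 and sham replicate 3, against -0.27 without FDG-decreased replicate 3 and -0.25 without sham replicate 1. Of the lists, 6 of 9 adipocyte markers were lower by 1 or more, and 2 of 6 without sham replicate 2, where the median was -0.52, against -1.98 without sham replicate 1. Of 25 xenobiotic genes 8 were higher by 1 or more (median 0.54), against 4 without FDG-decreased replicate 1, 1 without FDG-decreased replicate 2, 12 without FDG-decreased replicate 3 and 5 without sham replicate 3. Of 11 enterocyte markers 2 were higher by 1 or more, against 6 without FDG-decreased replicate 3, 8 without sham replicate 1, and 1 without FDG-decreased replicate 1, sham replicate 2 or sham replicate 3. In all, 137 of 10825 genes differed by 1 or more, 90 higher and 47 lower, around a median of 0.13 over all genes. The count was 413 without FDG-decreased replicate 1, 299 without sham replicate 2 and 492 without FDG-decreased replicate 3, the last with 439 higher and 53 lower. Without FDG-decreased replicate 2 the majority turned, with 42 higher and 51 lower.

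The comparisons share FDG-increased libraries, so chance alone gives differences of opposite sign. Over the 10652 genes tested in both, FDG-decreased minus FDG-increased correlated with FDG-increased minus sham at r = -0.597 (Spearman -0.534), across genes, which are not independent replicates. In 200 simulated draws of unchanged groups with the same shared libraries, the mean r was -0.135, with a range of -0.754 to 0.531. The covariance was -0.0773 against a simulated mean of -0.0132, a difference of -0.0641, within the simulated range of -0.0914 to 0.032. With no library shared, pair 3 of the RYGB table against the unshared FDG-increased library and the sham libraries gave r = -0.149. Atf3 and Fosb, higher in FDG-increased ileum on both sides, were the 2 genes called in both comparisons once the block was used. Independent lists would share 0.0278 genes, a value that leaves out the shared libraries. In 100 of the simulated draws fitted in the same way, 0 draws had a gene called in both with opposite signs by limma with Benjamini-Hochberg. Only 10 of these draws had any call in the RYGB table and 7 any in the sham table, so most could show no overlap. The draws hold no real change, and part of the overlap may come from the shared libraries. Without the block 0 genes were called in both, since limma called 0 in the RYGB table, with 110 there at an unadjusted p under 0.05. At an adjusted p under 0.1 by limma with Benjamini-Hochberg and with the block, 6 genes were called in both, Atf3, Fosb, Egr1, Hbegf, Dnajb1 and Sik1. Independent lists would share 0.112, again without the shared libraries, and 2 of the 100 simulated draws had genes called in both with opposite signs, up to 806 in 1 draw.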

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

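Chosen after seeing the data were the median shift, quantile normalization, the block without each pair, the unbridged tables and their lists and genes without each library, the lists without sham replicate 1, with quantile normalization, without shared members, without wrong synonyms or with the block and an estimated correlation, and the correlation with no library shared; the other settings were planned. Depth is unknown for FPKM, so no statement rests on counting error. Over the settings, 41 of the summary values kept to within 1.5 times (for the correlation, within 0.1) and 32 moved. For single named genes, 628 values kept their direction and side of the threshold, 90 passed it in addition, 31 no longer passed and 22 reversed. For each changed value below the cause was not tested, unless stated.

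For FDG-increased against sham ileum, limma called 4 genes. It called 1 with a pseudocount of 0.1, 0 with no filter on low values, 0 with quantile normalization, 10 at an adjusted p under 0.1 and 0 at an adjusted p under 0.01, the last pair by construction of the threshold; 847 genes had an unadjusted p under 0.05. Leaving out 1 library gave 0 to 13. With the replicate number as a block, 39 genes were called, 37 higher and 2 lower, the 4 among them. Here the replicate numbers share only a name: own-number correlations were 0.35, -0.50 and -0.25, and not every library correlated best with its own number.

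For FDG-decreased against FDG-increased ileum, limma called 0 genes, with 110 at an unadjusted p under 0.05, and 0 to 1 with 1 library left out. The replicate block, where same-numbered libraries deviated together, called 122. It called 35, 415 and 346 without replicates 1, 2 and 3 of both groups, which leaves 2 pairs. Of the calls the text gives for this comparison, the block changed none beyond those printed with a block value. For FDG-decreased against sham ileum, 137 genes differed by 1 or more, 232 with a pseudocount of 0.1, which widens differences of low genes by construction, and 93 to 492 with 1 library left out. No paired analysis was possible because that comparison comes from no test; its adjusted thresholds were not run for the same reason.

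Of the lists, camera called 22 and 18 in the tables. An estimated correlation left 0 and 0 and fry 0 and 0 (847 and 110 single genes at an unadjusted p under 0.05 by limma); the estimated correlation also left 0 without sham replicate 1 and 0 with the replicate block. The correlation of the comparisons went from -0.597 to -0.149 with no library shared, and 2 genes instead of 0 were called in both with the replicate block in the RYGB table.

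Reversed log2 differences, none of them called in either direction except Cyp3a18 with the block, came mostly from single libraries. In FDG-increased against sham ileum with 1 library left out, Slc2a2 ranged from -1.83 to 0.68, Slc5a1 from -0.34 to 1.02, Pkm from -0.44 to 0.29, Ldha from -1.12 to 0.23 and Egfr from -0.13 to 0.05; Slc5a1 was -0.38 with quantile normalization and Pkm 0.05 with lane 7 libraries only. In FDG-decreased against FDG-increased ileum with 1 library left out, Slc5a1 ranged from -0.22 to 1.01, Pkm from -0.22 to 0.27, Egfr from -0.34 to 0.09, Pyy from -0.87 to 0.28 and Slc10a2 from -2.26 to 0.03. Fabp6 ranged from -0.84 to 0.20 and was 0 with quantile normalization, and Cyp3a18 ranged from -0.15 to 1.74. With the block, Pkm was -0.21 without replicate 3 of both groups and Egfr 0.02 without replicate 1 of both groups.

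Lane as a term was not run for the sham table, since the lane of an FDG-increased library there is not known, and lane 7 alone was not run for the RYGB table, where it leaves 1 library against 1. The alternatives planned for counts or for comparison statistics do not apply to FPKM.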

Other observations

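The genes, patterns and tests in this part were all chosen after the results were seen, the counts of splits included. Genes of the heat-shock response, which protect or refold proteins, were not among the preset lists. Hspb1, a small heat-shock protein, stood at 209.1 ± 54.0 FPKM in FDG-increased and 36.8 ± 14.7 in sham ileum (SD, n = 3 each), a log2 difference of 2.53 (limma with Benjamini-Hochberg, adjusted p = 0.128). In the RYGB table Hspb1 fell with the block by 0.95 in FDG-decreased ileum (limma with Benjamini-Hochberg, adjusted p = 0.00595). Cryab, another small heat-shock protein, stood at 11.1 ± 0.503 FPKM in FDG-decreased and 34.8 ± 11.8 in FDG-increased ileum (SD, n = 3 each) and fell with the block by 1.5 (limma with Benjamini-Hochberg, adjusted p = 0.00595). Dnajb1 and Bag3, partners of the chaperone Hsp70, fell with the block by 0.67 and 0.77 (limma with Benjamini-Hochberg, adjusted p = 0.0439 and 0.0252). They differed by 2.03 and 1.63 between FDG-increased and sham ileum (limma with Benjamini-Hochberg, adjusted p = 0.096 and 0.257). These 4 genes were lower in FDG-decreased ileum in 3 of 3 pairs. Hspa1a and Hspa1b encode nearly the same Hsp70 protein, and how reads were divided between them is uncertain. Hspa1b differed by 4.18 between FDG-increased and sham ileum (limma with Benjamini-Hochberg, adjusted p = 0.152) and Hspa1a by 4.73 (limma with Benjamini-Hochberg, adjusted p = 0.308).

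S100g, called higher in FDG-increased than in sham ileum, is a target of the vitamin D receptor, whose own gene Vdr differed there by 0.04 (limma with Benjamini-Hochberg, adjusted p = 0.986). In RYGB ileum the level of S100g followed the replicate number more than the FDG group, at 249.5, 364 and 69.13 FPKM in FDG-decreased replicates 1 to 3 and 403.8, 515.6 and 84.26 FPKM in FDG-increased replicates 1 to 3. Hoxb9, a gene of position along the body, stood at 0.477, 2.02 and 0.074 FPKM in FDG-decreased replicates 1 to 3 and at 34.8, 31.9 and 0.608 FPKM in FDG-increased replicates 1 to 3 (log2 difference -2.88; limma with the block and Benjamini-Hochberg, adjusted p = 0.664). Against sham ileum it differed by 3.31, at 25.7 ± 14.6 against 3.32 ± 5.64 FPKM (SD, n = 3 each; limma with Benjamini-Hochberg, adjusted p = 0.473). No explanation of these values was tested.

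The higher immediate-early genes of FDG-increased ileum, in both comparisons, were weighed against 3 technical explanations. The list was also higher in contrasts with no shared library, pair 3 and the unshared FDG-increased library against sham. The list medians there, 0.86 and 1.83, both lay at percentile 100 of 10000 random lists. Each contrast holds a single FDG-increased library, and random lists ignore that these genes move together. The percentiles thus cannot tell a difference of the groups from the swing of a single library. For FDG-increased against sham ileum, the test of position covers only sham pieces taken nearer the duodenum, and that explanation is argued against. The list mean spanned only 0.49 over sham libraries whose proximal list mean spanned 2.65, while FDG-increased and sham ileum differed by 1.88. Most of the wider span came from sham replicate 1, at 4.98 against 3.23 and 2.32. In sham replicate 3 the proximal genes Lct and Gata4 were near the floor, at 0.317 and 0.0853 FPKM. The list thus cannot show FDG-increased pieces taken further from the duodenum than any sham piece, and that position stays open. For FDG-decreased against FDG-increased ileum the span over sham libraries says nothing, and position stays open. There the proximal list mean was higher in FDG-decreased ileum in each pair, at 3.33 against 2.17, 3.08 against 2.46 and 3.17 against 2.07. Handling of the tissue before freezing could raise the same genes and cannot be told apart from the FDG group: the FDG-increased library was higher in 3 of 3 pairs, and the labels give neither the time nor the order of dissection. The FDG group itself, which the design names, stays open and untested.

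Sham replicate 1 held 22.6 FPKM of Fabp6 where the other sham libraries held 8375 and 11350. A lower share of enterocytes is argued against, since the median of the other enterocyte markers was 1.69 higher there on the log2 scale. A swap with an RYGB library of these tables is argued against too, since the lowest Fabp6 among those was 5400 FPKM. A piece of intestine from nearer the duodenum is a candidate explanation and stays a hypothesis. With the genes that set this library apart left out, the 5 other proximal genes had a median 0.48 higher, at percentile 97.64 of 10000 random lists, and the 7 other bile acid genes one of -0.90, at percentile 0.01. No biological explanation was tested.

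Of the genes of the proximal intestine, 5 of 7 were higher in FDG-decreased than in FDG-increased ileum. By limma 0 passed over all genes without the block and 2 with it. The list was called higher by camera with Benjamini-Hochberg (adjusted p = 2.38e-06), but not with an estimated correlation (adjusted p = 0.209) or with ranks. Pieces taken nearer the duodenum in the FDG-decreased samples may give the higher values. The list's median lay at percentiles 100, 82.91 and 99.98 of random lists in pairs 1 to 3, so pair 2 leaves this explanation open. A higher share of enterocytes likewise stays open: of 20 abundant enterocyte genes, 10 were higher and 4 lower in 3 of 3 pairs, the 4 being Enpep, Fabp6, Naaladl1 and Slc51a. Neither can be told apart from the FDG group, which stays open and untested.

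Other splits of the same libraries are too few for a share under 0.05. For FDG-increased against sham ileum, 1 of 10 splits gave 4 or more genes, the real one, and the highest other gave 1. At an unadjusted p under 0.05 the real split did not stand out: limma had 847 genes there and 1793 and 929 in the splits with more. For FDG-decreased against FDG-increased ileum without the block the real value was 0, so 10 of 10 splits gave as many, and the highest other gave 1; limma had 110 genes at an unadjusted p under 0.05 in the real split and up to 2269 in other splits, which points to the structure by replicate number. With the block, 1 of 4 swaps of labels within pairs, the real one, gave 122 genes, and the highest other gave 0.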
